A study of Homo sapiens with 6 samples.

How the data were processed

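DNA methylation at CpG dinucleotides was measured by bisulfite sequencing of genomic DNA from PC-3 cells, an established human prostate carcinoma line. Of 6 samples, 3 had been given 160 µM S-adenosylmethionine (SAM, the methyl donor of cellular methyltransferases) and 3 had been given PBS as control, all for 5 days. Each sample has 1 deposited list of cytosine positions, with the strand and, per the file headers, the coverage as a count of reads and the percent of reads carrying C and T at that position. Bismark 0.7.4, methylKit 0.5.3, CASAVA 1.8.2 and FastQC 0.10.0 and the hg19 build are named per the submitters' processing notes, which give no role or order. The library type, the read filters and any removal of duplicate reads are not given in the sources used here. In each of the deposited lists the lowest coverage was 10 reads, so positions with fewer reads are not represented.

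Methylated read counts were recovered from the deposited coverage and percent C. The C of the minus strand was joined to the C of the plus strand 1 base before it, and both strands were summed. A CpG entered the comparisons when at least 10 reads covered it in all 6 samples, which held for 336571 of 1275871 CpGs listed in any sample (26.4%). Total reads over listed positions were 179379782, 36220663 and 120492978 in SAM replicates 1 to 3 and 150331703, 33056018 and 183523792 in control replicates 1 to 3. Median reads at the common CpGs were 108, 42 and 144 in SAM replicates 1 to 3 and 149, 37 and 127 in control replicates 1 to 3. Reads copied during amplification cannot be told from independent molecules in these counts, so read numbers overstate the precision.

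The mean methylation of the common CpGs, each weighted equally, was compared between groups with an exact two-sided permutation test, whose smallest possible p is 0.10 with 3 samples against 3. The same test was applied to 32 classes with Benjamini-Hochberg adjustment, namely 3 classes of mean level over all 6 samples, 4 classes of local density of listed CpGs in 1 kb windows, and 25 chromosomes. Single CpGs and 1 kb tiles with at least 3 CpGs were tested with the quasi-likelihood method of edgeR 4.0.16 (R 4.3.3) on methylated and unmethylated counts, with an adjusted p under 0.05. CpGs and tiles with 0 methylated or 0 unmethylated reads over all 6 samples were left out, which left 257696 CpGs and 33583 tiles. The test, the samples, the coverage minimum and the first group of other settings below were fixed before the data were examined, but the bounds of the density classes were not. The rule for naming sites and tiles, also fixed then, takes those past the threshold with the largest differences, up to 10 each way, and, when fewer than 5 pass, the 5 with the smallest p.

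Other settings tried were a minimum of 20 reads, each sample's own CpGs, weighting by coverage, strands kept apart, removal of CpGs over the 99.9th percentile of coverage, a replicate block, leaving out each sample, other minimum CpG numbers per tile, a minimum difference of 10 or 25 percentage points, a binomial logistic model with no overdispersion, and limma 3.58.1 on log2 ratios of methylated to unmethylated reads. Added after the data were seen were a quasi-binomial F test with moderated overdispersion, the edgeR likelihood ratio test with tagwise dispersion, 100 kb tiles, a stricter logistic threshold (adjusted p under 0.01 and at least 25 percentage points), and a batch found from read coverage. That batch was sought with edgeR on the mean reads of 57366 windows of 1 kb and strand, over all 10 splits of the 6 libraries into 3 and 3, and the 9 splits that do not follow it were tested again with the batch as a term. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used for the rest.

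The site and tile tests were tested on simulated data drawn from the real coverages, with 200 changed features. These were taken only from CpGs or tiles with a mean level of 30 to 70%, so the shares recovered do not cover other levels. With counting error as the only noise, edgeR's quasi-likelihood test recovered 81% of CpGs changed by 20 percentage points and 100% of those changed by 50 (29421 CpGs), and 99% and 100% of tiles (33431 tiles). A spread between libraries was then added at all levels, estimated from real CpGs or tiles with group means of 20 to 80%. With it, edgeR's test recovered 0% at both sizes among 24984 CpGs and 0% at both sizes among 32028 tiles. The quasi-binomial test then recovered 1% of CpGs changed by 20 points and 6% of those changed by 50, and 1% and 52% of tiles. The logistic model recovered 86% and 99% of CpGs with 14720 false calls, and 100% of tiles at both sizes with 22922 false calls. The coverage test, simulated with the spread inside the coverage batches on 57366 windows, recovered 23% of 4-fold and 99% of 16-fold changes. With the spread inside the treatment groups it recovered 2% and 42%.

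No gene annotation of hg19 was used here, since the table given names another assembly. Promoters, gene bodies and the 12 gene lists fixed beforehand were therefore not analysed here, and positions are given by hg19 coordinates without gene names. The labels do not state whether replicates came from separate cultures.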

Results

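CpG methylation was profiled in 6 PC-3 libraries, 3 from cells given 160 µM SAM for 5 days and 3 from cells given PBS. The libraries held 33056018 to 183523792 reads over listed positions, and 336571 CpGs were covered by at least 10 reads in all 6. Methylation levels of the same CpGs correlated between libraries with Pearson's r of 0.956 to 0.981, computed across CpGs, which are not independent replicates. The p-values below measure only the spread between these samples, which may be technical, because the labels do not say that replicates were separate cultures.

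The first comparison asked whether the methyl donor altered the overall methylation level of the cells. Mean methylation of the common CpGs was 38.4% ± 0.0171 (SD, n = 3) with SAM and 38.4% ± 0.0759 (SD, n = 3) in controls. The difference, SAM minus control, was 0.0197 percentage points with a standard error of 0.0449, and the groups overlapped (exact two-sided permutation p = 0.90). The smallest p this design allows is 0.10. Read coverage divided the libraries into 2 sets that cross the treatments, SAM replicate 1 with control replicates 1 and 3 (batch A) and SAM replicates 2 and 3 with control replicate 2 (batch B). Every batch A library also had more reads over listed positions than every batch B library, so the order of total reads cannot tell batch from depth. Median reads at the common CpGs did not follow the batches. They were 144 in SAM replicate 3 (batch B), against 108 in SAM replicate 1 and 127 in control replicate 3 (batch A). What part depth has in the split was not tested. The difference was 0.0547 points in batch A and -0.0217 points in batch B. Without control replicate 1 it was -0.0236 points. Weighting CpGs by coverage gave -2.06 points with a standard error of 3.63 (exact permutation p = 0.60). Using each library's own CpGs gave -1.08 points with a standard error of 2.04 (exact permutation p = 0.70). The groups overlapped in both.

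**Figure D1:**
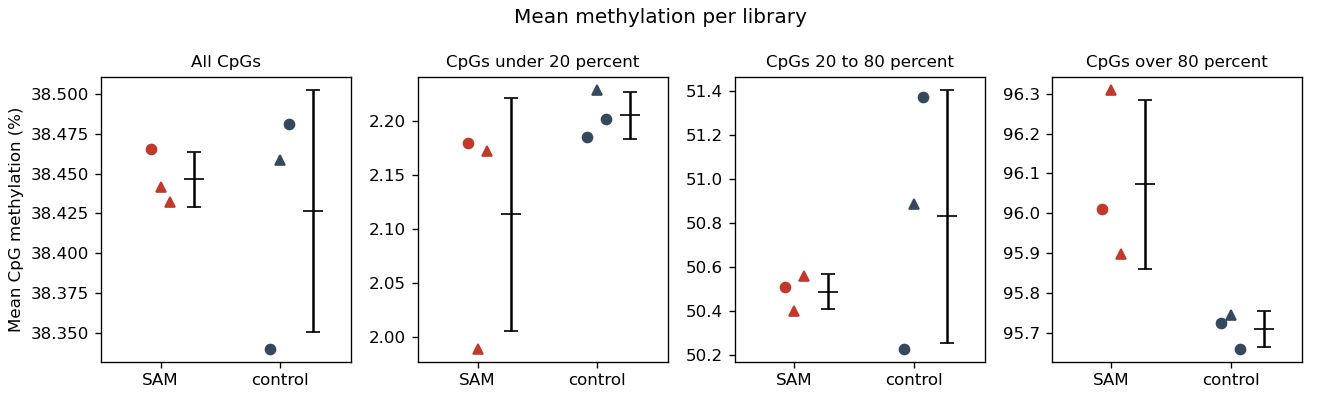
Mean CpG methylation in percent for each library, over all common CpGs and over 3 classes of mean level, with SAM libraries in red and controls in blue-grey, circles for batch A, triangles for batch B, and bars for mean ± SD (n = 3). Each panel has its own vertical scale that does not start at 0, and the groups do not overlap in the classes under 20 percent and over 80 percent.

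The second comparison divided the CpGs by level, density and chromosome. The 106974 CpGs with a mean level over 80% were at 96.1% ± 0.212 (SD, n = 3) with SAM and 95.7% ± 0.0443 (SD, n = 3) in controls, 0.364 points higher with a standard error of 0.125. The 184590 CpGs under 20% were at 2.11% ± 0.108 (SD, n = 3) with SAM and 2.21% ± 0.0218 (SD, n = 3) in controls, a difference of -0.0918 points. The 45007 CpGs between these levels were at 50.5% ± 0.0801 (SD, n = 3) and 50.8% ± 0.573 (SD, n = 3), and the groups overlapped (exact permutation p = 0.40). Their difference was -0.341 points, with -0.293 in batch A and -0.408 in batch B. It was -0.04 without control replicate 3 and -0.617 without control replicate 1, where the groups did not overlap. With coverage weights it reversed to 0.73 points, with overlapping groups. In windows with 1 to 4 listed CpGs per kb, 31201 CpGs stood at 72.8% ± 0.0412 (SD, n = 3) with SAM and 72.4% ± 0.169 (SD, n = 3) in controls. In windows with 40 or more, 130907 CpGs stood at 20.1% ± 0.0184 (SD, n = 3) and 20.2% ± 0.094 (SD, n = 3), and the groups overlapped (exact permutation p = 0.50). Their difference was -0.0538 points, with -0.0448 in batch A and -0.0578 in batch B, -0.00666 without control replicate 3 and -0.101 without control replicate 1, where the groups did not overlap.

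With 3 samples against 3 none of these classes could pass an adjusted threshold of 0.05. The groups did not overlap in 6 of 32 classes, each with the smallest possible exact permutation p of 0.10 and an adjusted p of 0.533. Chance gives 10% for a single class. The classes by level, density and chromosome hold the same CpGs of the same libraries and are not independent, so an excess over chance cannot be read from this. The 6 were the classes over 80% and under 20%, those with 1 to 4 and 5 to 14 listed CpGs per kb, and chromosomes 4 (0.25 points) and 19 (-0.115 points). With coverage weights the differences were 0.231 points over 80%, -0.197 under 20%, -1.43 at 1 to 4 and -1.77 at 5 to 14 listed CpGs per kb, -2.91 on chromosome 4 and -2.38 on chromosome 19. Of these only the class over 80% did not overlap. At a minimum of 20 reads the groups overlapped in 3 of the 6, namely CpGs under 20% (exact permutation p = 0.20), 5 to 14 listed CpGs per kb (exact permutation p = 0.20) and chromosome 4 (0.161 points, exact permutation p = 0.30). The 227 CpGs placed on chromosome Y had the largest difference of the 32 classes, 1.98 points (0.798 in batch A and 2.02 in batch B), with overlapping groups (exact permutation p = 0.20). It was 2.17 points at a minimum of 20 reads, where the groups did not overlap, and 0.86 points without SAM replicate 2. Whether the reads placed there came from a Y chromosome was not tested. Inside the coverage batches the class over 80% differed by 0.32 points in batch A and 0.359 points in batch B, and the class under 20% by -0.0143 and -0.148 points. The class with 1 to 4 listed CpGs per kb differed by 0.472 points in batch A and 0.242 in batch B, and the class with 5 to 14 by 0.219 and 0.0424. Chromosome 4 differed by 0.379 and 0.12 points, and chromosome 19 by -0.0776 and -0.115 points. Chromosome 4 differed by 0.165 points without control replicate 1, and chromosome 19 by -0.0749 points without SAM replicate 2. Without SAM replicate 2 the class over 80% differed by 0.226 points and the class under 20% by -0.0149 points, and the latter differed by -0.162 without SAM replicate 1 and -0.168 without SAM replicate 3. With class limits reset on the remaining libraries, the groups overlapped in the class under 20% without each library in turn except SAM replicate 3.

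The third comparison sought single CpGs and 1 kb tiles whose methylation differed between SAM and control. No CpG and no tile passed, with 0 of 257696 CpGs and 0 of 33583 tiles called by edgeR's quasi-likelihood test. At an unadjusted p under 0.05 that test gave 7244 CpGs and 1052 tiles, both less than a share of 0.05 of those tested. The other splits of the libraries gave 6699 to 7992 CpGs and 980 to 2453 tiles. Limma called 0 CpGs (8996 unadjusted) and 0 tiles (1420 unadjusted), and the quasi-binomial test called 0 CpGs (19571 unadjusted) and 0 tiles (2095 unadjusted). The unadjusted shares of limma also lay below 0.05 and those of the quasi-binomial test above it. Neither was counted for the other splits. The edgeR likelihood ratio test called 705 CpGs, 387 higher and 318 lower with SAM, and 135 tiles, 74 higher and 61 lower. It was neither simulated nor run on other splits of the libraries, so its rate of false calls is unknown. The logistic model without overdispersion called 74428 CpGs, of which 38680 were higher, 35745 lower and the rest equal in group means, and 13755 tiles, 7169 higher and 6586 lower. In simulations, the spread between libraries at CpGs or tiles of 20 to 80% was applied at all levels, and changes were made only at levels of 30 to 70%. There edgeR's quasi-likelihood test recovered 0% of 50-point changes among 24984 CpGs and 0% among 32028 tiles. The quasi-binomial test recovered 6% of them among the CpGs and 52% among the tiles. The logistic model made 14720 false calls among those CpGs and 22922 among those tiles, larger shares than it called in the real data. The simulations were thus noisier than the data and do not settle what edgeR's test could detect here. Its count of 0 is no evidence that such changes are absent.

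**Figure D2:**
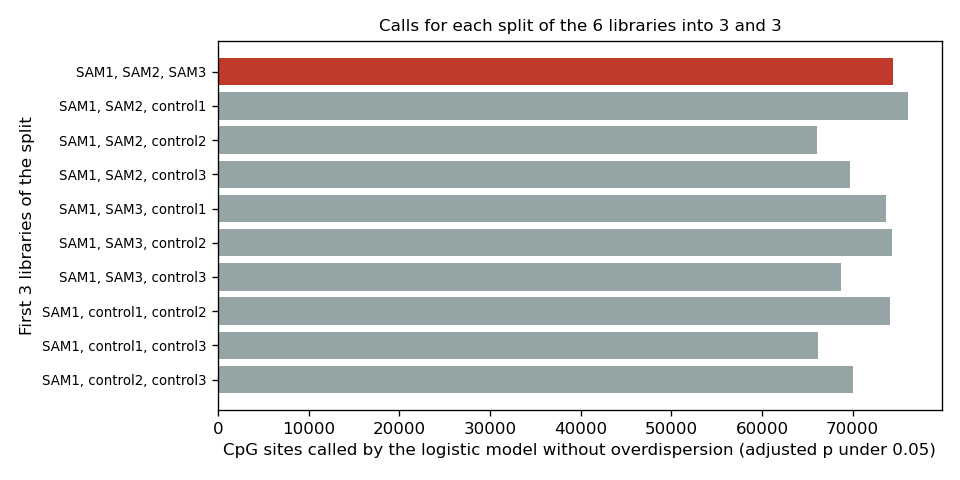
Number of CpGs called by the logistic model without overdispersion for each of the 10 splits of the 6 libraries into 3 and 3, with the split into SAM and control in red and the other splits in grey. The treatment split called 74428 CpGs and the other splits 66047 to 76047.

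The CpGs with the smallest p, none of which passed, lay at 3 neighbouring positions of chromosome 21 and at 1 position each of chromosomes 10 and 3 (hg19). At 9825992 on chromosome 21 methylation was 83.8% ± 4.04 (SD, n = 3) with SAM and 54.1% ± 2.5 (SD, n = 3) in controls, from 3790 to 77861 reads per library, a difference of 29.7 points (28.9 as the mean inside the batches). At 9825995 the levels were 83.6% ± 4.12 and 55.7% ± 2.28, and at 9825980 they were 69.99% ± 4.46 and 45.4% ± 2.95 (SD, n = 3 each). At 80733762 on chromosome 10 they were 0.0266% ± 0.0461 with SAM and 7.12% ± 1.7 in controls, from 53 to 1252 reads per library. At 106362603 on chromosome 3 they were 99.98% ± 0.0377 and 93.7% ± 2.06, from 118 to 1530 reads. Benjamini-Hochberg adjusted p from edgeR was 0.89 for all 5. The smallest adjusted p over all CpGs was 0.0701 without SAM replicate 2, 0.138 without SAM replicate 3 and 0.948 to 0.978 without each other library.

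The 3 chromosome 21 positions lie among the deepest of these data. Their 1 kb window, from 9825001 to 9826000, held on average 1.47% of the reads at common CpGs, and the next, from 9826001 to 9827000, held 5.64%. Whether the reads placed here all came from these positions of the genome was not tested. Leaving out the 654 CpGs of the highest coverage removes all 3. At these positions, in windows chosen after their values were seen, the strands differed. Over 7 CpGs from 9825975 to 9826010, minus-strand methylation was 73.6% ± 6.09 with SAM and 50.9% ± 0.472 in controls (SD, n = 3 each), while plus-strand methylation was 40.6% ± 8.51 and 42.6% ± 4.78. Both strands together differed by 22.8 points, with 24.1 in batch A and 21.7 in batch B. Minus-strand reads per CpG averaged 67721 with SAM and 18720 in controls, and plus-strand reads 225 and 269.6. Over the 8 CpGs before, from 9825933 to 9825964, minus-strand methylation was lower with SAM, at 49.97% ± 2.59 against 57.1% ± 2.39. Over the 6 CpGs after, from 9826019 to 9826047, it was 68.0% ± 3.91 with SAM and 58.2% ± 2.64 in controls, and plus-strand methylation was 55.8% ± 7.94 and 64.4% ± 0.169. These 6 were not alike. At 9826027 minus-strand methylation was 81.9, 84.4 and 66.1% in SAM replicates 1 to 3 and 52.4, 57.7 and 59.3% in controls. At 9826033 it was 56.0, 54.3 and 58.6%, and 56.5, 60.6 and 59.0%. Between these 2 positions minus-strand reads fell from 60445, 60366 and 152237 to 10237, 6197 and 56333 with SAM. In controls they fell from 39938, 37884 and 29938 to 22557, 21049 and 20112.

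**Figure D3:**
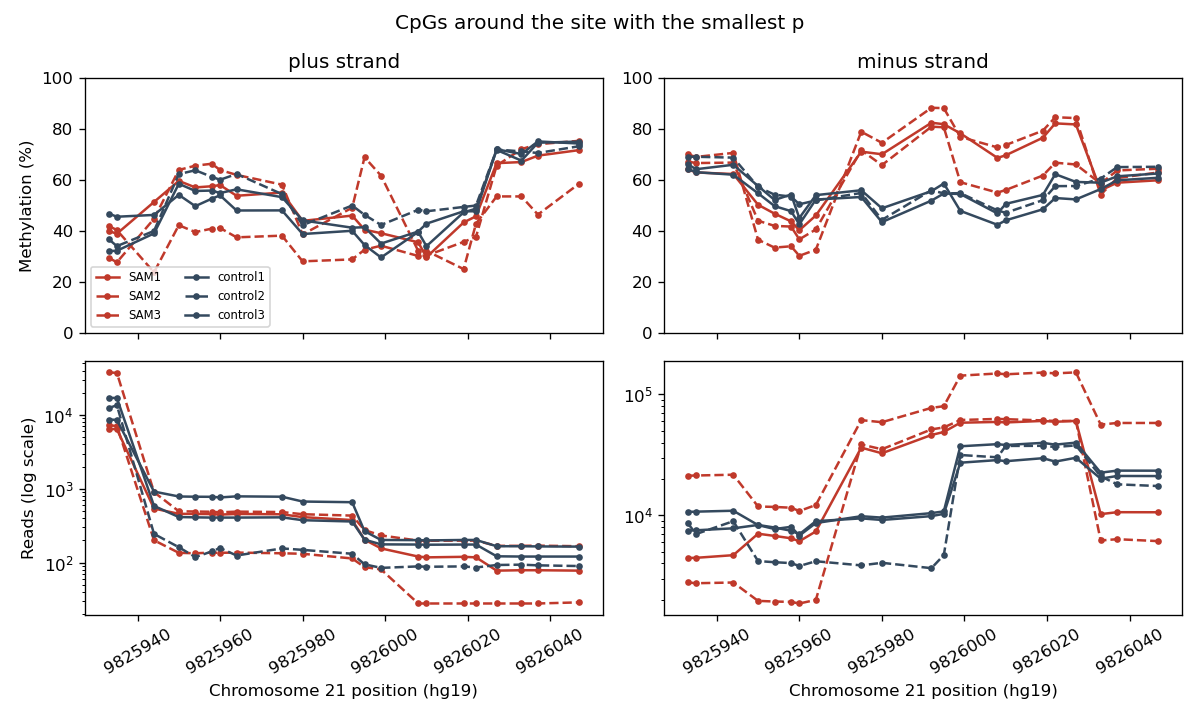
Methylation in percent and reads on a log scale at single CpGs of chromosome 21 (hg19), by strand, with SAM libraries in red, controls in blue-grey, solid lines for batch A and dashed lines for batch B. On the minus strand the 3 SAM libraries lie above the 3 controls at 9825992, and on the plus strand the groups overlap there.

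The tiles with the smallest p did not pass either, with an adjusted p from edgeR of 0.9999 for all 5. On chromosome 15 from 48938001 to 48939000 methylation was 99.99% ± 0.0224 with SAM and 97.6% ± 0.485 in controls (SD, n = 3 each). On chromosome 2 from 241514001 to 241515000 it was 99.93% ± 0.114 and 91.6% ± 2.48, and from 61698001 to 61699000 it was 0.00533% ± 0.00924 and 1.38% ± 0.937, a difference of -1.37 points that was -0.836 without control replicate 1. On chromosome 7 from 27192001 to 27193000 no methylated read was counted with SAM, and controls stood at 5.11% ± 0.178. On chromosome 20 from 36793001 to 36794000 the levels were 6.59% ± 1.06 with SAM and 0.0706% ± 0.122 in controls.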

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

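The quasi-binomial, likelihood ratio, stricter logistic, 100 kb and coverage batch tests were chosen after the results were seen. The edgeR quasi-likelihood count was 0 for CpGs and tiles at 20 reads, with minimum differences, the replicate block, each omitted sample and a coverage batch term. It was also 0 for CpGs with strands apart or without extreme coverage, and for tiles of 1 or 5 CpGs at least or 100 kb. These counts are no evidence of stability. That test recovered 0% of changes simulated at levels of 30 to 70% when the spread at 20 to 80% was applied at all levels (24984 CpGs, 32028 tiles). Limma and the quasi-binomial test gave 0. The logistic model called 74428 CpGs and 13755 tiles, its stricter form 3514 and 39, and the edgeR likelihood ratio test 705 and 135. In the other 9 splits the stricter form called 3319 to 3675 CpGs and 36 to 213 tiles. The likelihood ratio test was not run on those splits. The logistic counts may reflect a counting error set too small for the spread between libraries, since the other 9 splits called a median of 70020 CpGs and 14087 tiles. At CpGs of 30 to 70%, each library departed from the mean of the others with an SD of 13.2 to 24.8 points, where counting allows 4.55 to 8.66. The global difference reversed with each library's own CpGs (-1.08 points), with coverage weights (-2.06) and without control replicate 1 (-0.0236), and leaving out each sample gave -0.0236 to 0.0471. The coverage-weighted difference also reversed for CpGs of 20 to 80% (0.73), windows with 1 to 4 (-1.43) and 5 to 14 (-1.77) listed CpGs per kb, and for 14 of 25 chromosomes, among them chromosome 4 (-2.91). Of the 6 classes whose groups did not overlap, only CpGs over 80% stayed apart with coverage weights, and at a minimum of 20 reads CpGs under 20%, windows with 5 to 14 and chromosome 4 overlapped. The cause of these reversals was not tested beyond the read weights discussed under the other observations. The replicate numbers did not pair the samples, with correlations of deviations of -0.00509, 0.00846 and -0.00791 for equal numbers. The replicate block gave a global difference of 0.0197 points (exact sign-flip p = 1) and 0 calls. Promoter, gene body and gene list tests were not run. SAM replicate 2 and control replicate 2, with the fewest reads, listed the fewest CpGs (494389 and 505334).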

Other observations

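The tests on the class over 80%, on chromosome 21 and on the splits of the libraries were chosen after the results had been seen, and the 2 on the coverage-weighted level before. The bins held out from the comparison were tried after a look at bins set without SAM replicate 2, which had pointed the same way.

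The class over 80% was also divided by local density, and a trend over density was not tested. CpGs in windows with 1 to 4 listed CpGs per kb stood at 96.0% ± 0.227 (SD, n = 3) with SAM and 95.4% ± 0.102 (SD, n = 3) in controls, a difference of 0.609 points (0.565 in batch A and 0.56 in batch B). The differences were 0.428 points at 5 to 14, 0.266 at 15 to 39 and 0.144 at 40 or more listed CpGs per kb. The groups overlapped in the densest of these. Without SAM replicate 2 the 4 differences were 0.454, 0.306, 0.123 and 0.00542 points, from the sparsest to the densest. Without SAM replicate 3 the densest differed by 0.283 points, and the groups there did not overlap. By chromosome, 23 of 23 (1 to 22 and X) were higher with SAM in this class, by 0.186 to 0.487 points, and the groups did not overlap in 18. Without SAM replicate 2 the differences were 0.0859 to 0.373 points, and the groups did not overlap in 16. Chromosomes of the same libraries are not independent.

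CpGs over 80% stood 0.364 points higher with SAM. Bins set on noisy values are argued against by a mean difference of 0.307 points, above 0 in 9 of 9 pairings, when 1 SAM and 1 control library set the bins and the others were compared. Incomplete conversion is argued against because it would need CpGs under 20% to be 8.29 points higher with SAM, where the difference was -0.0918. The smaller difference inside the coverage batches was 0.32 points, but the class was followed up after its groups were seen not to overlap. The gap between the groups alone gives at least 0.154 in each batch, and each batch has 1 library on 1 side. The coverage batch therefore stays open. Misread bases in the control libraries stay open, with a held-out difference of 0.275 points at CpGs over 95% and 0.397 at 80 to 95%. An effect of SAM also stays open, untested.

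The chromosome 21 CpGs from 9825975 to 9826010 stood 22.8 points higher with SAM. The smaller difference inside the batches was 21.7 points, but the choice of the site by its p set this outcome, with a gap between the groups of 15.6 points, so the coverage batch stays open. A candidate explanation is extra minus-strand reads in the SAM libraries, and the plus-strand level differed by -1.94 points with overlapping groups. Minus-strand reads there, scaled to the total reads of each library, overlapped between groups with the batches pooled (exact permutation p = 0.20). Inside the batches they did not overlap. In batch A the scaled reads per CpG were 271 in SAM replicate 1, against 147 and 95.5 in control replicates 1 and 3. In batch B they were 1440 and 850 in SAM replicates 2 and 3, against 499 in control replicate 2. Each batch has 1 library on 1 side, so extra reads and a change on the minus strand cannot be told apart. Relative to the CpGs before, the minus-strand reads were 6.69 to 23.2 times as many in SAM libraries and 2.24 to 2.95 times in controls. This ratio was examined only after the pooled test left the question open.

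The coverage-weighted level ranged over 10.3 points between libraries, from 41.9% in SAM replicate 3 to 52.2% in control replicate 3. With 1 weight per CpG common to all libraries the range was 0.329 points, consistent with libraries spreading their reads differently over the same CpGs. A few CpGs of extreme coverage are argued against, since the range without them was 11.2 points. CpGs over 80% took 35.0 to 40.1% of reads in batch A and 29.3 to 30.7% in batch B.

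Coverage itself showed a structure of the samples. The split into batches A and B called 29710 of 57366 windows (51.8%), and the split into SAM and control called 0 by edgeR's quasi-likelihood test (142 at an unadjusted p under 0.05). With the batch as a term, SAM against control called 15 windows, 1 higher and 14 lower with SAM (2324 unadjusted). Of the 9 splits that do not follow the batch, 2 called at least 15 with the treatment split itself included. The other was the highest other count, 7666, for SAM replicates 1 and 2 with control replicate 3 against the rest. That split points to a further structure of the samples. The labels give no batch, and batch A holds the libraries with the most reads. With 9 or 10 splits no share under 0.05 can be reached, so the splits are too few to weigh chance. Without the batch term all 10 splits had as many windows as the treatment split, and the highest other count was 29710. For CpGs and tiles tested by edgeR's quasi-likelihood method, all 10 splits gave 0 calls, the highest other count included. For the logistic model, 2 of 10 splits, the treatment split included, called at least its 74428 CpGs, with a highest other count of 76047.

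Strand asymmetry, the mean absolute difference between strands at 7908 CpGs read on both, was 6.96 ± 1.32 points (SD, n = 3) with SAM and 7.05 ± 0.139 (SD, n = 3) in controls (exact permutation p = 0.80). Pooled reads carrying C at 20 mitochondrial CpGs were 0.289 to 0.399% across libraries, and whether they were unconverted or methylated was not tested. Most of these reads lay in 1 window of 5 CpGs, with 94404 to 687370 reads per library of 95770 to 691406. With each CpG weighted equally the level was 0.0877% in SAM replicate 3, the lowest, and 0.488% in control replicate 2, the highest. CpGs listed in all 3 SAM and no control library numbered 805, and in all 3 control and no SAM library 1802. CpGs listed in all of batch A and none of batch B numbered 135209, and the reverse 548. Batch A libraries held 150331703 to 183523792 reads and batch B libraries 33056018 to 120492978. The lists hold no position under 10 reads, so depth can enter such counts, and how much of them it gives was not tested. CpGs listed in SAM replicates 1 and 3 and control replicate 3, and in no other library, numbered 14825.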
